A study of Mus musculus with 6 samples.

How the data were processed

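Messenger RNA of epididymal white adipose tissue was measured by RNA sequencing in 6 mice kept on a high fat diet for 17 weeks, 3 wild type and 3 CD44 KO. Per the labels, total RNA was enriched for mRNA with oligo(dT) beads, made into NEBNext Ultra libraries and sequenced on a NovaSeq 6000. The submitters' notes name HISAT2, StringTie 1.3.1, RSEM and DESeq2 without saying what each was used for. The genome build, the annotation and the strandedness of the libraries are not given in the sources used here. Each library was taken as 1 mouse and grouped by the genotype in its label.

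The authors deposited 1 table with expected counts and FPKM per gene and library. Its expected counts are estimated counts per gene that were not scaled, and 7.57% to 8.3% of the values in a library were not whole numbers. The authors' FPKM are scaled for transcript length and library size and were rounded by the authors to 2 decimals. A comparison table that the authors deposited repeats the expected counts after rounding, with 0 genes that differ, and adds a log2 fold change, p-values and adjusted p-values per gene. The authors' log2 fold change equals the log2 ratio of the group means of FPKM, each mean floored at 0.001. The tables list 22322 genes, of which 22267 (99.75%) have an Ensembl identifier in GENCODE M21 (GRCm38) and 21744 are protein coding there. Positions given for genes are those of that annotation, matched by identifier.

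The expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 13829. Libraries were scaled by TMM, dispersions were estimated, and CD44 KO was compared with wild type by the quasi-likelihood F-test (glmQLFit with robust estimation, glmQLFTest) with Benjamini-Hochberg adjustment over all genes tested. "edgeR adjusted p" below means this adjusted p, and a gene was called at a value under 0.05. CPM (library-scaled counts) are TMM-normalised, and errors of CPM are SD over 3 libraries. Errors of log2 fold changes (SE) are the absolute log2 fold change divided by the square root of the F statistic. The 95% intervals of folds come from that error with 4 residual degrees of freedom. The test moderates its degrees of freedom, so an interval and a p-value can differ. A fold against a group with no counts was set against a floor of 3 counts over the group. Total expected counts per library ran from 15543317 to 18765009, and at this depth 15776 to 16915 genes had at least 1 count. PCR reads without molecular identifiers are not independent molecules, so such floors cover counting error only.

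The 32 gene lists, the rule for naming genes, the tests and most of the alternatives were fixed before the data were examined. The lists cover cell types (pan-macrophage, lipid-associated macrophage, tissue-resident macrophage, T and NK cell, B cell, neutrophil, dendritic cell, mature adipocyte, fibroblast and adipocyte progenitor, endothelial, mesothelial, epididymis, skeletal muscle, smooth muscle). They also cover programs (inflammatory cytokines and chemokines, MHC class II, de novo lipogenesis, lipolysis and triglyceride synthesis, fatty acid oxidation, nuclear-encoded OXPHOS, thermogenic adipocyte, extracellular matrix and fibrosis, hyaluronan and CD44 ligands and partners). The others are cell cycle, insulin signalling, hypoxia response, ER stress and unfolded protein response, interferon response, immediate early genes, circadian clock, mitochondrially encoded transcripts and the chromosomal neighbours of Cd44. The 29 lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists ("camera adjusted p"). Each list was also tested with the correlation estimated from the data and with fry. A library's list score is the mean over tested members of log2 CPM after subtracting each gene's mean over the 6 libraries. Gene-level counts of a list are given over all genes tested and adjusted over the list alone.

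Called genes with a mean of at least 1 CPM and no overlap between the groups were eligible for naming. Unnamed gene models, symbols that mark pseudogenes, and immunoglobulin and T cell receptor segments were left out. Genes named in the text were taken from Cd44, then the 12 largest increases and the 12 largest decreases among the eligible genes. To these come up to 4 members of lowest p from each list and 15 genes fixed by name: Lep, Adipoq, Pparg, Adgre1, Itgax, Trem2, Tnf, Ccl2, Spp1, Has2, Col1a1, Col6a3, Ucp1, Fasn and Slc2a4. Not every gene the rule takes is described. Other genes are said to have been chosen after their values were seen.

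Genes called higher and genes called lower were tested separately for KEGG pathways and GO terms, using the annotation in the deposited table, by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. The background was all tested genes with an annotation (5949 for KEGG and 13269 for GO), and terms with 10 to 500 members in it were tested (318 and 2327).

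Alternatives to the fit, run 1 at a time, were RLE factors or library size alone in place of TMM, no low-count filter or a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a fit without robust estimation, a 2-fold minimum, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) of genes with a mean FPKM of at least 0.5, and the former without a filter. DESeq2 brings its own scaling and tested 18178 genes, and the FPKM fits change the unit, the test and the filter together (13309 genes with the filter). The replicate number was also used as a block, a prior count of 0.5 was used for the list tests, and each library was left out in turn. Leaving out wild type replicate 2 and CD44 KO replicate 2 together was added after seeing the data, and so was an edgeR fit with the pan-macrophage score, as mean log2 CPM, as a covariate beside the genotype.

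The steps were tested on simulated data made from these libraries. Of 196 genes changed among 13603, the edgeR step called 0% of those changed 2-fold, 56% at 4-fold, 85.4% at 8-fold and 87.8% at 16-fold, and 8.9% of its 123 calls were false. All 5 raised lists among 30 were called by camera, with 0 of the other 25. Genes were drawn independently of each other in this simulation, so it does not show how camera does with correlated members. In the data the estimated correlation reached 0.911, in the MHC class II list. With 20 random gene sets the enrichment step called 1 term, and it called 20 of 20 planted terms. No library was left out of the main comparison. P-values of the gene-level tests measure the spread between these libraries, and the labels do not say whether mice shared a litter or a cage. Camera p-values with the preset correlation and Fisher p-values compare genes with other genes, so they do not measure the spread between mice.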

Results

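RNA was sequenced from the epididymal white adipose tissue of 6 mice, 3 wild type and 3 lacking CD44, after 17 weeks on a high fat diet. CD44 is a cell surface receptor for hyaluronan carried by leukocytes and stromal cells, and the comparison of the genotypes addresses its function in white fat. Total expected counts were 16692760, 18517945 and 18765009 in wild type replicates 1 to 3 and 16665450, 17790847 and 15543317 in CD44 KO replicates 1 to 3.

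Cd44 itself (ENSMUSG00000005087, minus strand of chromosome 2 from 102811141 to 102901665 in GRCm38) was almost lost from the knockout fat. It stood at 355 ± 197 CPM (SD, n = 3) in wild type and at 2.29 ± 0.675 CPM in CD44 KO, with 3091, 10580 and 6000 expected counts against 28, 50 and 34. This was a 155-fold decrease (95% interval 51.1 to 468), with a log2 fold change of -7.27 (SE 0.58) and a Benjamini-Hochberg adjusted p of 0.0126 in the edgeR quasi-likelihood test. Without wild type replicate 3 the edgeR adjusted p of the Cd44 log2 fold change was 0.122, and without CD44 KO replicate 3 it was 0.0785. Over all alternatives it ran from 5.79e-49 to 0.122, and the log2 fold change from -7.58 to -5.79.

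Gene groups that differed as sets by camera between fat without CD44 and wild type fat included matrix, macrophage, adipocyte, insulin pathway, clock and mesothelial genes. Of 29 lists tested, 17 passed camera with the preset correlation and 0 with an estimated correlation. By fry 5 passed, the matrix and mesothelial lists (fry adjusted p 0.0456 each) and the progenitor, insulin signalling and clock lists (0.0235 each). The pan-macrophage, lipid-associated macrophage and mature adipocyte lists did not pass fry (0.167, 0.166 and 0.131). Of 13829 genes tested, 240 were higher and 122 lower in CD44 KO by the edgeR quasi-likelihood test, and 216 and 112 of these changed at least 2-fold. In all 362 the 3 libraries of each genotype did not overlap. Among all genes tested 37.8% did not overlap, where chance gives 10%. These counts depended on single libraries: they were 248 and 62 without wild type replicate 1, 2 and 7 without wild type replicate 2, and 0 and 0 without wild type replicate 3, where 2386 genes had an unadjusted edgeR p under 0.05 (4292 with all libraries). They were 1007 and 1363 without CD44 KO replicate 1, 64 and 36 without CD44 KO replicate 2, and 5 and 2 without CD44 KO replicate 3, and all 362 genes kept their sign in each of these 6 fits. Calls within the gene lists followed these counts: in no list did the fits without wild type replicate 2, wild type replicate 3 or CD44 KO replicate 3 call more than 1 gene. The mean correlation of log2 CPM across genes, which are not independent replicates, was 0.932 between CD44 KO replicate 1 and the wild type libraries and 0.908 between it and the other CD44 KO libraries. CD44 KO replicate 2 held epididymis transcripts, described with the mesothelial genes.

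Large decreases were seen in genes of a matrix protease, an enzyme of serotonin synthesis and a proton channel. Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975), the matrix protease stromelysin, fell from 22.7 ± 4.3 to 0.306 ± 0.1 CPM, a log2 fold change of -6.18 (SE 0.32, edgeR adjusted p 0.004). Its call held in 5 of the 6 fits that each left out 1 library. Tph2 (ENSMUSG00000006764, chromosome 10, 115078641 to 115185022), an enzyme of serotonin synthesis, fell 358-fold, from 142 ± 109 to 0.393 ± 0.164 CPM (log2 fold change -8.48, edgeR adjusted p 0.0242). Otop1, a proton channel gene, had 289, 208 and 252 counts in wild type and 2, 4 and 1 in CD44 KO (log2 fold change -6.53, SE 0.46). Timp1, an inhibitor of matrix proteases, fell by 4.75 on the log2 scale, and Saa3, an acute-phase protein gene with close paralogs, fell by 6.17. Cck, which encodes cholecystokinin, Pvalb and Trdn, which encode the calcium proteins parvalbumin and triadin, Hephl1 and the lipase gene Lipf had log2 fold changes of -7.61, -6.84, -6.56, -4.97 and -4.68. Without wild type replicate 1 Tph2, Cck and Saa3 stood at -7.70, -6.63 and -5.22, without CD44 KO replicate 1 Timp1 and Lipf stood at -5.93 and -5.42, and without CD44 KO replicate 2 Pvalb stood at -7.50. Mstn (myostatin) and Art2a, an ADP-ribosyltransferase gene with a close paralog, had no counts in any CD44 KO library and were at least 35.5-fold and at least 35.8-fold lower. GENCODE M21 lists Art2a as a polymorphic pseudogene, which its symbol does not show, so the naming rule kept it.

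Large increases were seen in genes of an acyl-CoA synthetase and a protein secreted by adipocytes. Acsm3 (ENSMUSG00000030935, chromosome 7, 119760923 to 119787513), a medium-chain acyl-CoA synthetase, rose 149-fold, from 0.349 ± 0.073 to 52.8 ± 23 CPM (log2 fold change 7.22, SE 0.50, edgeR adjusted p 0.00857). Cfd (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), the complement protease adipsin secreted by adipocytes, rose 27.1-fold to 9896 ± 4352 CPM (log2 fold change 4.76, SE 0.85, edgeR adjusted p 0.0473). Without wild type replicate 1 its log2 fold change was 5.82, and its call held in 2 of the 6 fits that each left out 1 library. The other genes of this group given here were near 0 in wild type. Ggt1, which cleaves glutathione outside cells, had 0, 2 and 0 counts there and 122, 144 and 27 in CD44 KO, and the D-amino acid oxidase gene Dao had 0, 1 and 0 against 55, 52 and 16. Baiap2l2 had 2, 0 and 1 against 36, 36 and 34. Calml3, Dcdc2a, Ppp1r1b, Greb1 and Fn3k had log2 fold changes of 7.35, 5.83, 5.03, 4.66 and 4.65. Calml3 and Ppp1r1b stood at 8.01 and 6.15 without wild type replicate 2, Greb1 and Fn3k at 5.65 and 5.38 without wild type replicate 1, Dcdc2a at 5.09 without CD44 KO replicate 1, and Calml3 and Greb1 at 6.30 and 4.01 without CD44 KO replicate 2.

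**Figure D1:**
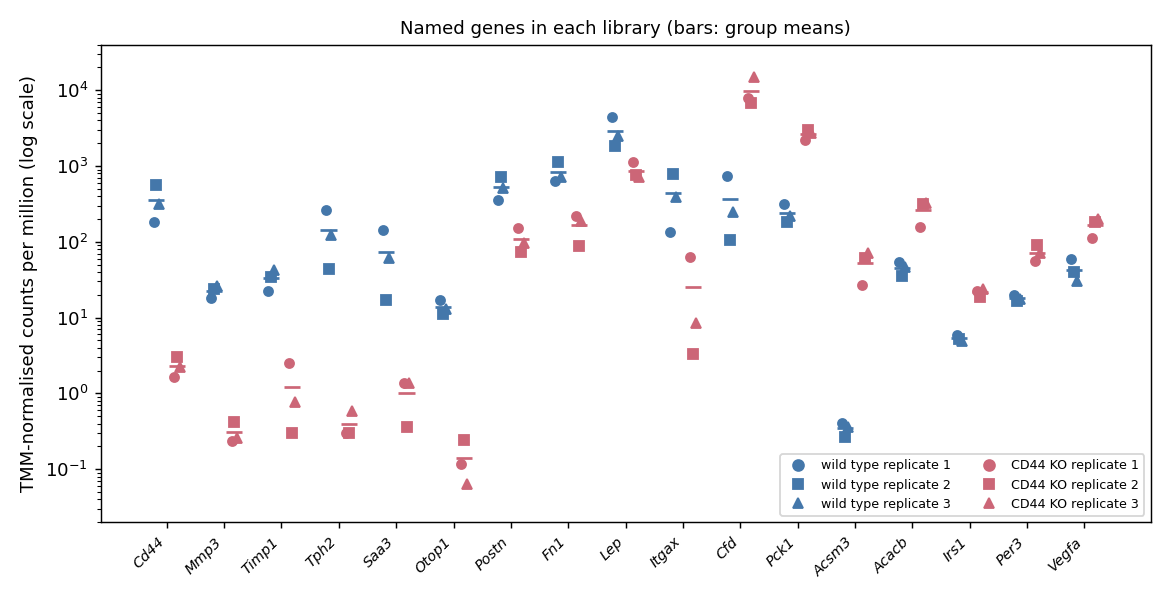
TMM-normalised CPM (log scale) of 17 named genes in each library, with wild type in blue, CD44 KO in red, a symbol per replicate and a bar at each group mean. Cd44 stood at 182 to 570 CPM in wild type and 1.66 to 3 CPM in CD44 KO, and Itgax at 63.7 CPM in CD44 KO replicate 1 against 3.36 and 8.42 CPM in the other CD44 KO libraries.

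Genes of the extracellular matrix were lower in CD44 KO fat almost throughout the list. Of 28 tested members 6 fell and 0 rose over all genes tested, 23 fell adjusted over the list alone, and 27 had negative log2 fold changes (median -1.83, camera adjusted p 5.09e-11; adjusted p = 0.603 with an estimated correlation). The proteoglycan gene Bgn fell from 698 ± 102 to 187 ± 60.4 CPM (log2 fold change -1.90, SE 0.28, edgeR adjusted p 0.0356). Postn (periostin) fell from 531 ± 184 to 108 ± 40.3 CPM and Fn1 (fibronectin) from 824 ± 262 to 164 ± 67.4 CPM, with edgeR adjusted p of 0.0409 and 0.0462. The other 3 that fell were Timp1, Col5a2 and the collagen crosslinking enzyme gene Lox (log2 fold change -1.97 and -1.84 for the last pair, chosen after their values were seen). Col1a1 and Col6a3 had log2 fold changes of -2.46 and -2.25 with edgeR adjusted p of 0.0759 and 0.0554, and without CD44 KO replicate 1 Col1a1 stood at -3.31 and was called. The library scores of the list were 0.82, 0.97 and 0.86 in wild type and -0.30, -1.52 and -0.83 in CD44 KO, and edgeR called 3 lower without wild type replicate 1, 20 without CD44 KO replicate 1, 2 without CD44 KO replicate 2 and 0 without any 1 of the other libraries.

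Partners of CD44 and stromal progenitor markers were lower as sets, with 1 gene called. Of 19 tested genes for hyaluronan handling and CD44 ligands, edgeR called 0 (7 lower and 0 higher at an unadjusted p under 0.05, 5 lower by DESeq2, and 0 adjusted over the list alone). The list's median was -0.78 (camera adjusted p 0.012; adjusted p = 0.603 with an estimated correlation). Its lowest p belonged to the scavenger receptor gene Stab2 (log2 fold change -2.21, edgeR adjusted p 0.0615; called at -2.88 without CD44 KO replicate 1), and the hyaluronan synthase gene Has2 stood at -0.62 (edgeR adjusted p 0.429). Of 14 fibroblast and adipocyte progenitor markers 1 fell, Pi16 (log2 fold change -1.89, edgeR adjusted p 0.0499), and adjusted over the list alone 2 fell and 1 rose. This list was lower as a set with a median of -0.61 (camera adjusted p 0.0271; adjusted p = 0.603 with an estimated correlation), but not without CD44 KO replicate 1 (camera adjusted p 0.0784). Without that library edgeR called 5 hyaluronan genes and 2 progenitor markers lower.

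Macrophage genes were lower in 2 of the 3 CD44 KO libraries and close to wild type replicate 1 in the third, and antigen presentation genes were lower in all 3. All 15 pan-macrophage markers had negative log2 fold changes (median -2.13). Their median was -3.52 without CD44 KO replicate 1 and -1.63 without CD44 KO replicate 2. The library scores were 0.65, 1.66 and 1.58 in wild type and 0.60, -3.04 and -1.44 in CD44 KO. edgeR called 0 of the 15 (4 lower at an unadjusted p under 0.05, 5 lower by DESeq2, and 0 adjusted over the list alone), and the list was lower by camera (adjusted p 0.000117; adjusted p = 0.672 with an estimated correlation). Of 17 markers of lipid-associated macrophages, lipid-laden cells of fat, 16 were negative (median -2.11, camera adjusted p 0.000117; adjusted p = 0.672 with an estimated correlation). That median was -3.85 without CD44 KO replicate 1 and -1.36 without wild type replicate 2 and CD44 KO replicate 2 together. Of the 17 markers edgeR called 0 over all genes (9 lower and 1 higher at an unadjusted p under 0.05, 10 and 1 by DESeq2), and 6 lower and 1 higher adjusted over the list alone. Itgax, which encodes CD11c, stood at 436 ± 323 CPM in wild type and 25.2 ± 33.5 in CD44 KO (log2 fold change -4.11, SE 1.27, edgeR adjusted p 0.103). Trem2, Adgre1 and Spp1 had log2 fold changes of -2.67, -2.24 and -0.64 with edgeR adjusted p of 0.257, 0.266 and 0.811. Itgax stood at -3.38 without wild type replicate 2. Without CD44 KO replicate 1 Itgax stood at -6.21 (edgeR adjusted p 0.0241) and these 3 at -6.25, -5.00 and -4.43, without CD44 KO replicate 2 these 3 stood at -2.11, -1.69 and -0.06, and the former fit called 12 of the 15 pan-macrophage and 13 of the 17 lipid-associated macrophage genes lower. All 9 MHC class II genes were negative (median -1.48, camera adjusted p 0.00142; adjusted p = 0.672 with an estimated correlation), with 0 called by edgeR, 5 lower at an unadjusted p under 0.05, 5 lower by DESeq2, 1 lower adjusted over the list alone and 2 lower without CD44 KO replicate 1. The MHC class II scores were 1.1, 0.43 and 0.90 in wild type and 0.04, -2.03 and -0.45 in CD44 KO.

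Resident macrophage markers, cytokines and cell cycle genes were also lower as sets, with their lowest scores (-1.67, -1.85 and -1.68) in CD44 KO replicate 2. The 15 tissue-resident macrophage markers had a median of -0.62 (camera adjusted p 0.0118; adjusted p = 0.672 with an estimated correlation). edgeR called 0 of them (3 lower at an unadjusted p under 0.05, 3 lower by DESeq2, and 0 adjusted over the list alone), and the set call was lost without wild type replicate 1 (camera adjusted p 0.0587) and without CD44 KO replicate 2 (0.13). Among 15 cytokine and chemokine genes 1 fell, Saa3, over all genes and adjusted over the list alone, while Tnf and Ccl2 had log2 fold changes of -2.22 and -1.61 (edgeR adjusted p 0.105 and 0.177), and Ccl2 was called at -2.56 without CD44 KO replicate 1. Their median was -0.94 (camera adjusted p 0.0267; adjusted p = 0.672 with an estimated correlation), and the set call was lost without CD44 KO replicate 2 (camera adjusted p 0.242). All 23 cell cycle genes were negative (median -1.35, camera adjusted p 1.04e-05; adjusted p = 0.672 with an estimated correlation). The median of the 23 was -2.8 without CD44 KO replicate 1 and -0.9 without CD44 KO replicate 2. None of the 23 was called by edgeR (4 lower at an unadjusted p under 0.05, 0 by DESeq2, and 0 adjusted over the list alone), and their score in CD44 KO replicate 1 was 0.70, above the 0.32 of wild type replicate 1. With the pan-macrophage score as a covariate the medians of these 3 lists turned positive (0.06, 0.14 and 0.17), and 0 cell cycle genes had an unadjusted p under 0.05. The score differs between the genotypes, and that fit kept 6 of the 362 called genes as calls. It therefore cannot decide whether macrophages account for these decreases. Without CD44 KO replicate 1 edgeR called 19 cell cycle genes, 5 tissue-resident macrophage markers and 2 cytokine genes lower.

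Adipocyte genes were higher in CD44 KO fat, with leptin as the exception. Of 15 mature adipocyte markers 14 were positive (median 1.01), 1 rose over all genes (Cfd), and 7 rose and 1 fell adjusted over the list alone. The list was higher by camera (adjusted p 0.000207; adjusted p = 0.672 with an estimated correlation). Lep stood at 2927 ± 1378 CPM in wild type and 870 ± 241 in CD44 KO (log2 fold change -1.75, SE 0.41, edgeR adjusted p 0.0682). Adipoq, Pparg and the insulin-regulated glucose transporter gene Slc2a4 had log2 fold changes of 1.01, 0.88 and 1.90 with edgeR adjusted p of 0.2, 0.149 and 0.106, and the beta-adrenergic receptor gene Adrb3 had 4.30 with 0.056. Without wild type replicate 1 Adipoq, Slc2a4 and Adrb3 stood at 1.64, 2.88 and 5.61, the latter 2 called. Of 16 genes of lipolysis and triglyceride synthesis 1 rose over all genes and 6 adjusted over the list alone (median 1.00, camera adjusted p 0.0235; adjusted p = 0.672 with an estimated correlation). That gene was Pck1 (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), whose enzyme supplies glycerol 3-phosphate in fat, at 240 ± 68.1 CPM in wild type and 2631 ± 422 in CD44 KO (log2 fold change 3.45, SE 0.31, edgeR adjusted p 0.0196). The set call of this list was lost without wild type replicate 2 (camera adjusted p 0.0908) and without CD44 KO replicate 1 (0.054). Without the latter edgeR called 4 of its genes higher, and 4 adipocyte markers higher and 1 lower, and without wild type replicate 1 it called 3 and 5 higher.

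Insulin pathway genes were higher, while genes of fatty acid synthesis went both ways. Of 15 insulin signalling genes 3 rose over all genes, and 10 rose and 1 fell adjusted over the list alone (median 0.94, camera adjusted p 0.00238; adjusted p = 0.603 with an estimated correlation). The insulin receptor substrate gene Irs1 rose from 5.32 ± 0.459 to 21.5 ± 2.58 CPM (log2 fold change 2.01, SE 0.18, edgeR adjusted p 0.0196). Pde3b, which encodes a phosphodiesterase that insulin activates, and the insulin receptor gene Insr rose by 1.66 and 1.11 on the log2 scale (edgeR adjusted p 0.0461 and 0.048). Of 15 de novo lipogenesis genes 2 rose over all genes, and 4 rose and 1 fell adjusted over the list alone, with no set call (camera adjusted p 0.364). Its median was -0.03 while its mean was 0.40 and camera's direction was up. The 2 were Acacb, an acetyl-CoA carboxylase gene that rose from 45.6 ± 9.92 to 266 ± 93.1 CPM (edgeR adjusted p 0.0309), and the carbohydrate-responsive transcription factor gene Mlxipl (log2 fold change 1.86). Fasn stood at -0.80 (edgeR adjusted p 0.167). Without CD44 KO replicate 1 edgeR called 7 insulin signalling genes higher and 1 lower and 4 lipogenesis genes higher, and without CD44 KO replicate 2 it called 1 and 0.

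Mitochondrial transcripts were higher, with no set call for fatty acid oxidation or thermogenic genes. All 13 mitochondrially encoded transcripts were positive (median 1.70, camera adjusted p 1.04e-05; adjusted p = 0.603 with an estimated correlation), and mt-Atp6 and mt-Cytb had log2 fold changes of 1.76 and 2.11. edgeR called 0 of the 13 over all genes (11 higher at an unadjusted p under 0.05, 11 by DESeq2) and 11 adjusted over the list alone, and it called 5 without CD44 KO replicate 1. With the pan-macrophage score as a covariate their median was 0.71 and 0 had an unadjusted p under 0.05. Because the score differs between the genotypes, that fit cannot decide whether macrophages account for the increase. The most abundant transcript, mt-Co1, took 1.79% to 2% of counts in wild type and 3.31% to 5.52% in CD44 KO. The 26 nuclear-encoded OXPHOS genes had a median of 0.34 (camera adjusted p 0.00556; adjusted p = 0.704 with an estimated correlation), and edgeR called 0 (6 higher at an unadjusted p under 0.05, 2 by DESeq2, and 0 adjusted over the list alone). That set call was lost without wild type replicate 2 (camera adjusted p 0.0936) and without CD44 KO replicate 3 (0.0768). Of 17 fatty acid oxidation genes 1 fell, the muscle-type carnitine transferase gene Cpt1b (log2 fold change -2.55, edgeR adjusted p 0.0402), over all genes and adjusted over the list alone, and the set was not called (camera adjusted p 0.905). Of 13 thermogenic genes the coactivator gene Ppargc1a and Ebf2 rose by 2.24 and 1.44 on the log2 scale and Otop1 fell, 3 rose and 2 fell adjusted over the list alone, and the set was not called (median -0.76, camera adjusted p 0.363). Ucp1, the uncoupling protein of brown fat, was too low to test, with 9, 10 and 12 counts in wild type and 1, 0 and 0 in CD44 KO.

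Output genes of the circadian clock were higher in all 3 CD44 KO libraries. Of 15 clock genes 4 rose over all genes, and 10 rose and 1 fell adjusted over the list alone (median 1.06, camera adjusted p 0.00228; adjusted p = 0.603 with an estimated correlation). Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665), a period gene, rose from 18.2 ± 1.77 to 72.1 ± 16.9 CPM (log2 fold change 1.99, SE 0.21, edgeR adjusted p 0.0242). The transcription factor genes Tef, Dbp and Hlf rose by 1.32, 1.51 and 2.19 on the log2 scale (edgeR adjusted p 0.0266, 0.0434 and 0.0461). The clock activator genes Arntl, Npas2 and Clock, chosen after their values were seen, had log2 fold changes of -1.30, -1.79 and -0.30 (edgeR adjusted p 0.0898, 0.145 and 0.212). Npas2 stood at -1.01 without wild type replicate 2, and Arntl was called at -1.57 without CD44 KO replicate 1. Without CD44 KO replicate 1 edgeR called 6 clock genes higher and 1 lower, and without CD44 KO replicate 2 it called 2 higher. Times of tissue collection are not given in the sources used here.

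Hypoxia and unfolded protein response genes showed single changes without a set call. Of 12 hypoxia genes the angiogenic factor gene Vegfa and Ndrg1 rose by 1.95 and 1.40 on the log2 scale (edgeR adjusted p 0.0415 and 0.0315), and 3 rose and 1 fell adjusted over the list alone. Hif1a stood at -0.64, the median was -0.25, the mean was 0.16 and camera's direction was up (camera adjusted p 0.905). Of 14 unfolded protein response genes 1 rose, over all genes and adjusted over the list alone, the asparagine synthetase gene Asns (log2 fold change 1.68, edgeR adjusted p 0.0266; camera adjusted p 0.433). The 14 endothelial markers were all positive (median 0.44, camera adjusted p 0.045; adjusted p = 0.704 with an estimated correlation), with 0 called by edgeR, 1 higher at an unadjusted p under 0.05, 0 by DESeq2 and 0 adjusted over the list alone. This set call was lost without wild type replicate 2 (camera adjusted p 0.276), wild type replicate 3 (0.0978), CD44 KO replicate 2 (0.0945) or CD44 KO replicate 3 (0.286), and with the pan-macrophage score as a covariate the median turned to -0.26 (quartiles -0.32 and -0.15). That score differs between the genotypes, so the turn does not show a cause.

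Mesothelial markers, genes listed for the epithelium that covers the fat pad, were higher in every CD44 KO library. All 11 were positive without overlap between the genotypes, where 37.8% of all genes tested did not overlap. Over all genes 1 rose, and adjusted over the list alone 11 rose. The list had a median of 2.86 (camera adjusted p 1.04e-05, and adjusted p = 0.603 with an estimated correlation). Its median was 3.71 without wild type replicate 2 and 2.4 without wild type replicate 3. Krt19 rose from 0.855 ± 0.359 to 10.8 ± 6.82 CPM (log2 fold change 3.66, SE 0.65, edgeR adjusted p 0.0473), and Krt18 had a log2 fold change of 7.26 (edgeR adjusted p 0.0748), which was 4.24 without CD44 KO replicate 2 and 7.98 without wild type replicate 2. Without CD44 KO replicate 1 edgeR called 4 mesothelial genes higher, and without CD44 KO replicate 2 it called 0. Whether transcripts of listed keratin genes such as Krt18 and Krt19 came from mesothelium or from epididymis cannot be told in these libraries. The mesothelial surface genes Msln and Upk3b, chosen after their values were seen, had 20, 14 and 1 and 65, 80 and 3 counts in wild type, against 76, 72 and 42 and 370, 317 and 173 in CD44 KO. CD44 KO replicate 2 also held transcripts of the epididymis: 160218 counts of the sperm-coat gene Crisp1, against 12 to 28 in the other libraries, and 20088 of Adam7, against 182 and 78 in the other CD44 KO libraries and 2 or 3 in wild type. Only these 2 of 18 epididymis genes could be tested, and edgeR called 0 of them over all genes (2 higher at an unadjusted p under 0.05, 0 by DESeq2) and 2 adjusted over the list alone, 2 without CD44 KO replicate 1 and 1 without CD44 KO replicate 2.

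**Figure D2:**
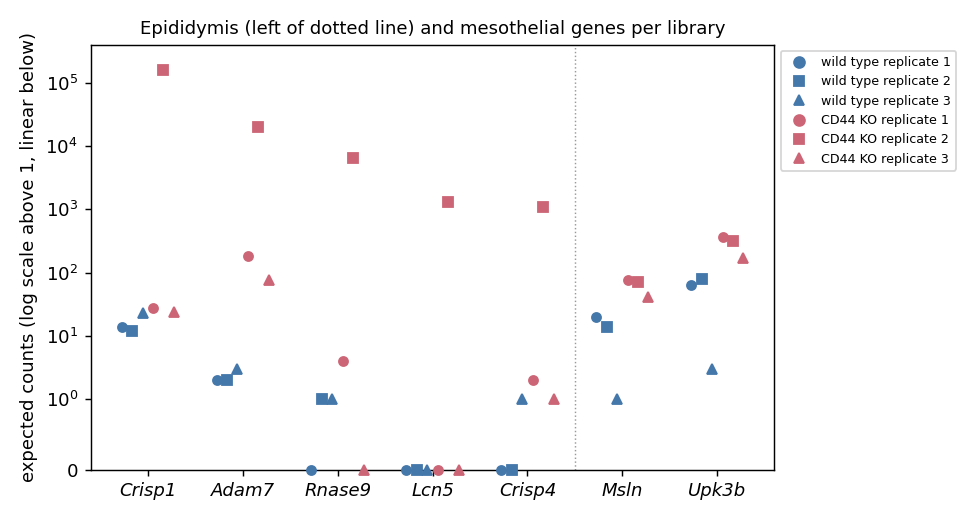
Expected counts (log scale above 1, linear below) of 5 epididymis and 2 mesothelial genes in each library, with wild type in blue, CD44 KO in red and a symbol per replicate. Crisp1 reached 160218 counts in CD44 KO replicate 2 and 12 to 28 elsewhere, whereas Msln and Upk3b were above every wild type library in all 3 CD44 KO libraries.

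**Figure D3:**
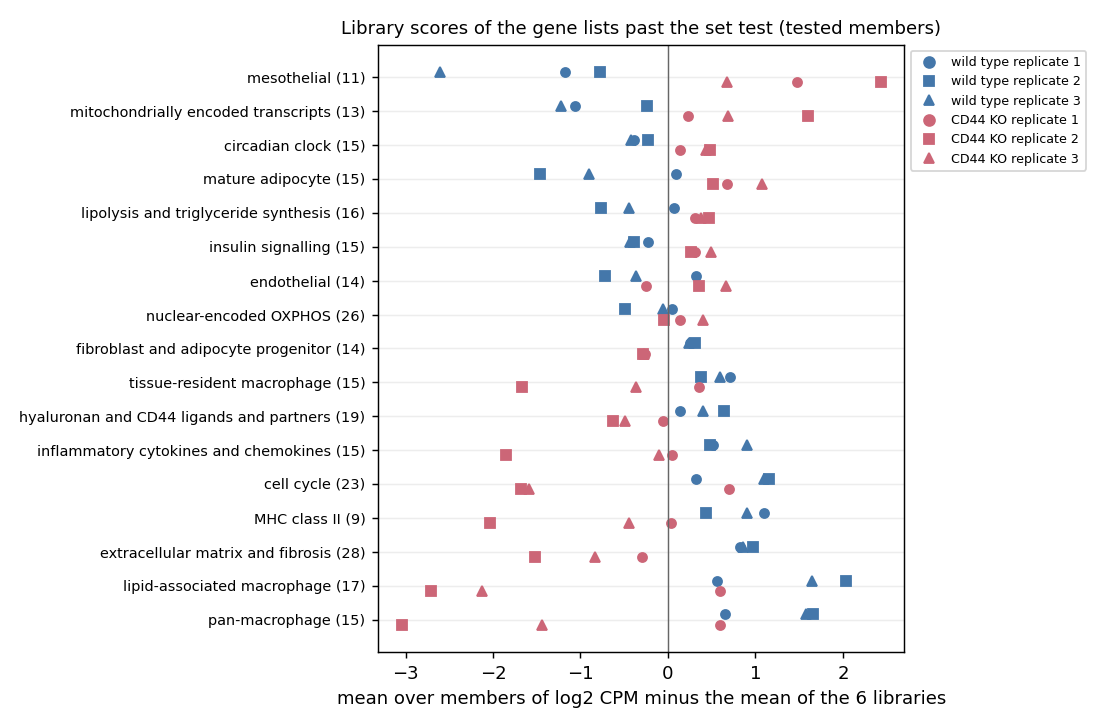
Library scores (mean over tested members of log2 CPM minus the mean of the 6 libraries) of the 17 lists that passed the set test, with the number of tested members in brackets, wild type in blue, CD44 KO in red and a symbol per replicate. The matrix list separated the genotypes (0.82 to 0.97 against -1.52 to -0.30), whereas the pan-macrophage score of CD44 KO replicate 1 (0.60) lay beside that of wild type replicate 1 (0.65).

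Genes beside Cd44 on chromosome 2 gave no set call. Of 17 tested neighbours 1 fell, the complement inhibitor gene Cd59a (104095801 to 104115354), from 203 ± 80.3 to 29.2 ± 3.68 CPM (log2 fold change -2.80, SE 0.34, edgeR adjusted p 0.0266). Adjusted over the list alone 3 rose and 2 fell, with a median of 0.09 and a camera adjusted p of 0.905. Camera tests a shift in a common direction, so changes that go both ways would not give a call. Of the 17 neighbours 9 did not overlap between the genotypes, beside 37.8% of all genes tested. Cd59a has a close paralog, and how reads shared between paralogs were assigned is not given in the sources used here.

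Annotated terms named glutathione, insulin and fatty acid metabolism among the genes called higher. By a one-sided Fisher's exact test with Benjamini-Hochberg adjustment, 7 KEGG pathways were enriched, among them insulin resistance (9 of 100 genes, adjusted p 0.0218), insulin signaling (9 of 126, 0.0414) and butanoate metabolism (5 of 21, 0.0136). Glutathione metabolism (6 of 53, Fisher adjusted p 0.0414) rested on Ggt1, Gpx3, Gsta4, Gstt1, Gstt2 and Gstt3, chosen after their values were seen, of which the last 3 are paralogs. Gpx3, a secreted glutathione peroxidase gene, rose by 3.63 on the log2 scale and Gstt1 by 2.13 (edgeR adjusted p 0.0461 and 0.0261), and Gpx3 stood at 2.80 without CD44 KO replicate 2. The other pathways were glucagon signaling, renin secretion and drug metabolism by cytochrome P450. Several of the 7 pathways shared genes and are not separate results. Insulin resistance, insulin signaling and glucagon signaling all held Acacb, Pck1 and Ppargc1a, among others. Drug metabolism shared Gsta4, Gstt1, Gstt2 and Gstt3 with glutathione metabolism. GO gave 3 terms, acyl-CoA (5 of 19 genes), fatty acid (12 of 153) and glutathione (7 of 51) metabolic processes, with Fisher adjusted p of 0.0213, 0.0213 and 0.0238. Genes called lower gave 0 KEGG pathways (lowest Fisher adjusted p 1) and 4 GO terms. The GO terms were cell adhesion (15 of 388 genes, Fisher adjusted p 0.00324), extracellular matrix organization (8 of 123, 0.0139), acute-phase response (4 of 21, 0.0229) and positive regulation of peptidase activity (3 of 10, 0.0435). With the genes called lower by DESeq2 as input there were 24 KEGG pathways, led by lysosome (46 of 120 genes, Fisher adjusted p 1.12e-10) and phagosome (50 of 151, 3.24e-09), and 68 GO terms, and with those called higher 31 and 18.

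The authors' deposited comparison called more genes than the edgeR test on the same counts. At the authors' adjusted p under 0.05 it listed 1354 genes higher and 1325 lower, which included all 240 and all 122 of the edgeR calls with 0 in the opposite direction. With a 2-fold minimum as well it listed 949 and 933, of which 210 and 115 were edgeR calls. The log2 fold changes of the authors and of edgeR had a Pearson correlation of 0.994 across genes, which are not independent replicates. DESeq2 run on the same counts called 1487 higher and 1459 lower. The log10 p-values of that DESeq2 run and of the authors had a Pearson correlation of 1 across genes.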

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

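All tests weighed in this part were chosen after the results were seen, and so were the split of the clock list and the use of the genes called higher, while the lists themselves were fixed beforehand.

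CD44 KO replicate 2 held a signal among genes too low elsewhere to enter any comparison: 16 epididymis genes outside the tests summed to 8969 counts there, against 16, 5 and 6 in wild type and 57 and 17 in the other CD44 KO libraries. Of the 18 listed epididymis genes 6 reached 100 counts in this library and at most 1 in any other, led by Crisp1 (160218), Adam7 (20088), Rnase9 (6422), Lcn5 (1297) and Crisp4 (1103), while Gpx5 had 0. A candidate source is epididymis tissue collected with the fat of this mouse, which stays open: no sort separates cells here, the count of 6 genes only restates the signal, and no biological explanation was tested. Of the 240 genes called higher 57 were also called without this library. The other 183, no longer called with fewer libraries, had a median log2 fold change of 1.54 (quartiles 1.16 and 2.19) without it against 1.53 with it. These values cannot decide whether epididymis RNA was a source of the increases. Genes called higher showed no overlap between the genotypes, so each was already above wild type in the other CD44 KO libraries. Leaving out this library also did not remove all epididymis signal, since Adam7 kept a log2 fold change of 5.88. The mesothelial list kept a median of 2.59 (1.34 to 4.24) without CD44 KO replicate 2, where more mesothelium collected with the knockout fat stays open and was not tested. For the keratin genes of that list epididymis as a source stays open as well.

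The matrix list was lower in CD44 KO. A larger share of adipocyte RNA that dilutes all other cell types alike would lower endothelial and matrix genes together. The endothelial minus matrix score differed between the genotypes by 2.27, with -0.50, -1.69 and -1.22 in wild type and 0.05, 1.86 and 1.5 in CD44 KO (exact two-sided permutation p 0.1, the smallest that 3 against 3 allows). Both directions were known when this score was formed. The endothelial scores alone overlapped, with 0.32, -0.72 and -0.36 in wild type and -0.25, 0.35 and 0.66 in CD44 KO. Matrix genes thus fell relative to endothelial genes, which does not exclude dilution as a part of the cause. Whether fewer macrophages were the whole cause could not be decided. With the pan-macrophage score as a covariate the median log2 fold change went from -1.83 to -0.92 (quartiles -1.27 and -0.79). In that fit 16 of the 28 genes had an unadjusted edgeR p under 0.05. The score is an imperfect measure of macrophages and differs between the genotypes, so part of a macrophage effect may stay with the genotype. That fit has 3 residual degrees of freedom in place of 4 and kept 6 of the 362 called genes as calls, so most calls ended, while all 362 kept their sign. A whole or partial role of macrophages stays open, as do fewer matrix-producing fibroblasts and an effect of the genotype within fibroblasts, which were not tested.

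The clock list was higher in CD44 KO. A different time of day at collection cannot be told apart from the genotype, because collection times are not given in the sources used here. The mean of the other 12 clock genes minus that of the 3 activators differed by 2.12 between the genotypes, with -0.27, -1.64 and -1.27 in wild type and 0.80, 1.06 and 1.32 in CD44 KO (exact two-sided permutation p 0.1, the smallest possible). Those 12 were all positive (median 1.21) and the activators had a median of -1.3, opposite signs that a shift of phase may give. The 12 kept a median of 0.92 (quartiles 0.57 and 1.3) with the pan-macrophage score as a covariate. As for the matrix list, that fit cannot decide whether fewer macrophages were the whole cause, because the score is an imperfect measure of macrophages.

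The 6 libraries allow 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 362 genes and 17 lists, 1 of 10 splits gave as many of either, and the highest other split gave 0 genes and 15 lists.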

How the results depend on the processing

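The fit without wild type replicate 2 and CD44 KO replicate 2, the libraries farthest apart on the first principal component, was chosen after the results were seen. So was the fit with the pan-macrophage score as a covariate, and all other alternatives were planned. Against 240 genes higher and 122 lower, the tests gave 145 and 85 with no low-count filter (18497 genes tested), 1487 and 1459 by DESeq2, 56 and 56 by limma-trend on log2(FPKM + 1) without a filter, and 0 and 0 with the replicate number as a block in edgeR (2805 genes at an unadjusted p under 0.05). The block tests a pairing that the labels do not state, and the deviations of same-numbered libraries correlated at -0.32, -0.22 and -0.02 across genes. Without the 2 libraries together edgeR gave 0 and 0 (2481 at an unadjusted p under 0.05). Leaving out each library gave 0 to 1007 higher and 0 to 1363 lower. RLE factors, library size, the stricter filter, voom, the fit without robust estimation, the 2-fold minimum and filtered FPKM stayed within 1.5 times both counts, and the 362 genes kept their sign under every alternative that tested them. The Cd44 log2 fold change was -7.17 with the block (edgeR adjusted p 0.0543), -7.00 without the 2 libraries (0.0634) and -7.58 to -6.75 over the fits without 1 library, where its call was lost without wild type replicate 3 or CD44 KO replicate 3, and the call held under all other alternatives. Of 17 lists called, 0 were called with an estimated correlation and 5 by fry, 14 to 16 were kept with a library left out (15 to 18 lists called in all), and all 17 were kept under RLE, library size, a prior count of 0.5 and the block, which also called the T and NK cell and dendritic cell lists lower (camera adjusted p 0.00462 and 0.0437). Of 51 called genes checked singly, 29 stayed called with no filter, 36 by voom, 14 by FPKM without a filter, 51 by DESeq2 and 0 with the block. Spp1, not called in any fit, had a log2 fold change of 0.41 without the 2 libraries, against -0.64. Terms called numbered 141 with DESeq2 calls as input, against 14. Except for the filters, which change the number of genes tested, and the fits with fewer libraries, the cause was not tested. In simulations at this depth and number of libraries 2-fold changes were called in 0% of genes and 8-fold changes in 85.4%, so a gene not called here is not shown to be unchanged. The simulation changed 196 of 13603 genes. In the data 4292 of 13829 had an unadjusted edgeR p under 0.05, so the simulated rates may not carry over.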

Other observations

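Lymphocyte, dendritic cell and neutrophil markers gave no call in either direction over all genes. Of 15 T and NK cell markers 12 were negative (median -0.47, camera adjusted p 0.069), and edgeR called 0 (1 lower at an unadjusted p under 0.05, 1 lower by DESeq2, and 0 adjusted over the list alone). Without wild type replicate 2 (0.00221) or CD44 KO replicate 3 (0.00711) that camera adjusted p passed, over a range up to 0.439, and the T cell receptor gene Trac had a log2 fold change of -1.78 (edgeR adjusted p 0.08). B cell and plasma cell genes went both ways: of 6 tested, Igkc stood at 2.35 and Ighm at -2.00, edgeR called 0 over all genes (3 higher and 2 lower at an unadjusted p under 0.05 and by DESeq2), and 3 rose and 2 fell adjusted over the list alone (camera adjusted p 0.905). Without CD44 KO replicate 1 edgeR called 2 of these lower, with Ighm at -2.79, and without CD44 KO replicate 2 it called 2 higher, with Igkc at 2.87, while Igkc stood at 1.58 without CD44 KO replicate 3. The 10 dendritic cell markers had a median of -0.64 (camera adjusted p 0.0832, and 0.0245 without CD44 KO replicate 3), with Irf8 at -1.76 (called at -2.73 without CD44 KO replicate 1), 0 called by edgeR, 1 lower and 1 higher at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 adjusted over the list alone. Only 4 of 10 neutrophil genes could be tested, with S100a8 at -2.47 and S100a9 at 2.83 (-3.61 and 0.66 without CD44 KO replicate 3), 0 called by edgeR, 1 higher and 1 lower at an unadjusted p under 0.05 and by DESeq2, and 0 adjusted over the list alone.

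Interferon, immediate early and muscle genes showed no set call either. The 21 interferon response genes had a median of -0.05 (camera adjusted p 0.363, and 0.0235 without CD44 KO replicate 3), with Oasl2 at -0.91, and edgeR called 0 (1 higher and 3 lower at an unadjusted p under 0.05, 2 lower by DESeq2, and 0 adjusted over the list alone). The 15 immediate early genes, which respond to tissue handling, had a median of 0.87 (camera adjusted p 0.187, and 0.00987 without CD44 KO replicate 2), with Egr2 at -2.06 (called at -2.55 without CD44 KO replicate 1), and edgeR called 0 (5 higher and 2 lower at an unadjusted p under 0.05, 3 and 2 by DESeq2, and 0 adjusted over the list alone). The 9 smooth muscle genes had a median of 0.67 (camera adjusted p 0.117, and 0.0169 without wild type replicate 1), with Lmod1 at 1.48 (called at 1.94 without wild type replicate 1 and also without CD44 KO replicate 1), and edgeR called 0 (3 higher at an unadjusted p under 0.05, 1 by DESeq2, and 1 adjusted over the list alone). Of 11 skeletal muscle genes 3 could be tested, of which Pvalb fell and Actn3 stood at 1.88 (edgeR adjusted p 0.076), and 1 rose and 1 fell adjusted over the list alone.

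Albumin, chosen after its values were seen, also differed between single libraries: Alb had 27, 7 and 5 counts in wild type and 90, 1100 and 6007 in CD44 KO (edgeR adjusted p 0.0698). Genes more than 8-fold above every other library numbered 480 in CD44 KO replicate 2, 40 in CD44 KO replicate 3, 3 in CD44 KO replicate 1 and 1, 1 and 0 in wild type replicates 1 to 3.

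With the pan-macrophage score as a covariate, a fit chosen after the results were seen, 12 of the 17 called lists kept the sign of their median and 5 turned. Those that turned were the endothelial list, 3 given in the report (tissue-resident macrophage, cytokine and cell cycle genes) and the pan-macrophage list, from which the score was made (-2.13 to 0.13). Medians went from -2.11 to -0.48 for lipid-associated macrophage, from -1.48 to -0.60 for MHC class II, from -0.78 to -0.24 for hyaluronan and from -0.61 to -0.34 for progenitor genes. They went from 1.00 to 0.54 for lipolysis and triglyceride synthesis, from 0.94 to 0.69 for insulin signalling and from 2.86 to 2.46 for mesothelial genes, and stood at 0.99 for adipocyte genes (1.01 without the score) and at 0.34 with and without it for nuclear-encoded OXPHOS genes. Among lists not called, smooth muscle genes went from 0.67 to -0.27, T and NK cell markers from -0.47 to 0.05 and dendritic cell markers from -0.64 to 0.09. The score is an imperfect measure of macrophages and differs between the genotypes, so these shifts do not show a cause.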
